A study of Homo sapiens with 8 samples.

How the data were processed

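Total RNA from 2 doxycycline-inducible (Tet-ON) derivatives of the human breast cancer line MCF7 was labelled with Cy3 and hybridised to 8 single-colour Agilent arrays of 60-mer probes on 3 slides. Per the labels, 1 line carried HIC1 and the other the miR-212/132 cluster, and each was grown in EMEM with 10% fetal calf serum, 0.01 mg/ml insulin and G418 at 100 ug/ml, with or without 1 ug/ml doxycycline for 36 h. The labels call the 2 arrays of a group replicates, and the series' design text speaks of 2 independent experiments without saying which arrays belong to which.

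Per the file headers, the authors' arrays were read by Agilent Feature Extraction 10.5.1.1, which wrote for every spot a processed signal in intensity units, after subtraction of background and spatial detrending within the array, with low values replaced by a surrogate and no scaling between arrays. The deposited raw spot signal and the local background were also in intensity units, and the spot flags held only 0 and 1. The deposited series table held log2 values with no stated scaling or centring. From the values, each of its columns was log2 of the processed signal plus 1 constant per array, between -0.2 and 0.245. Between 99.82% and 99.87% of the probes of an array lay within 0.01 of that constant, and the median of every column was 6.69. The table was thus median-centred per array, not centred per gene, and not a ratio, so that a higher value meant a brighter probe.

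Of 45015 spots per array, 1639 were control spots and were left out. Spots of the same probe were averaged, which left 41000 probes, and spots marked as non-uniformity or population outliers were set to missing, which left 133 probes without a value on at least 1 array. Probes were given current gene symbols from a list of human RefSeq gene names. The accession in the file named 26386 probes, the symbol 2399 and a synonym 596, and 11619 kept the name printed in the file. No genome or transcript sequence was at hand, and probe coordinates are those the files give on hg19. A probe entered if it was well above background on both arrays of at least 1 group and had a value in every group, which left 29510 probes. The probe with the highest mean over all arrays stood for its gene, which gave 21082 genes, of which 14478 had a current symbol and 6123 had more than 1 probe entering.

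The log2 processed signal minus the 75th percentile of its array was fitted with limma 3.58.1 (R 4.3.3, data.table at 1.17.8, statmod at 1.5.0), with 1 coefficient for each of the 4 groups over all 8 arrays and empirical Bayes moderation (4 residual and 2.03 prior degrees of freedom). The comparisons were doxycycline against none in the HIC1 line, the same in the miR-212/132 line, the difference between these responses, and the uninduced HIC1 line against the uninduced miR-212/132 line. All tests were two-sided, and a gene passed at a Benjamini-Hochberg adjusted p below 0.05 within a comparison. Errors given after ± are standard errors from limma unless said otherwise. The number of arrays limits the precision. A gene not well above background on both arrays of 1 group is reported as at least N-fold changed. That bound sets the mean of the brighter group against, for each dim array, the higher of the lowest well-above-background signal on that array and the probe's own signal.

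Before the data were examined, 33 gene lists with 861 genes were fixed, of which 796 were tested. They covered reported targets of HIC1 and of miR-132/212, the 17p13.3 neighbours of both loci, HIC1 partners and BTB zinc fingers, ephrins and Eph receptors, estrogen response, G1/S and DNA replication, G2/M and mitosis, replication-dependent histones, p53 targets, apoptosis regulators, interferon-stimulated genes, NF-kB and inflammatory genes, ATF4 and integrated stress response, unfolded protein response chaperones, heat shock, NRF2 oxidative stress, metallothioneins and zinc transport, autophagy and lysosome, cholesterol biosynthesis, fatty acid synthesis, hypoxia and glycolysis, oxidative phosphorylation, mitochondrial ribosome, cytosolic ribosomal proteins, epithelial and luminal, mesenchymal and EMT, basal and myoepithelial, immune cell, and fibroblast and endothelial markers, Wnt and TCF targets, TGF-beta targets, and immediate early and AP-1 genes. The lists were tested with limma's camera at a preset inter-gene correlation of 0.01, over 21031 genes with a value on every array, with Benjamini-Hochberg adjustment over the 33 lists of a comparison. camera was run again with a correlation estimated from the residuals, and fry was run as a test of each list on its own. The estimate lay below the preset 0.01 for some called lists, such as estrogen response (-0.01), basal and myoepithelial (-0.062) and cholesterol biosynthesis (-0.012). Their calls still had a higher p in that run. A call lost with an estimated correlation thus cannot be put down to list members moving together alone. The genes named were chosen by a rule fixed with the design. They were HIC1, then for each comparison the 12 highest and 12 lowest log2 fold changes among passing genes with a symbol that moved the same way in both pairs of arrays of equal number, then up to 4 members of each list with the smallest p. Other genes are said to have been chosen after their values were seen.

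The alternatives fixed with the design were normexp background correction (offset 50), quantile normalization, centring on the median, the deposited log2 table itself, no filter on dim probes, only probes well above background on all 8 arrays, outlier spots kept, every probe as its own feature, the slide as a random or a fixed block, a replicate block, the 4 arrays of a comparison alone, trended and robust moderation, the other tests of the lists, and each array left out in turn. With the slide as a random block, the lists were tested by a preranked form of camera on the moderated t values. The list test thus changed together with the model, and the slide correlation fitted there was negative (-0.1386). A list call lost in that setting cannot be put down to the slide alone. Alternatives chosen after seeing the data were normexp with its background taken from the negative control spots (offset 50 as well), the brightest probes without HIC1 DOX+ replicate 1, and the search for miRNA seed sites within the probe sequences in place of the planned search of 3' UTRs. The offset adds 50 units to every signal, which by itself shrinks the folds of dim probes. The method was tested on simulated data made from the spread of these arrays, with 50 genes changed at each size. At log2 changes of 0.5, 1, 2 and 4 it recovered 2, 26, 40 and 48 genes in the HIC1 line (4%, 52%, 80% and 96%), beside 12 false calls. In the miR-212/132 line it recovered 3, 30, 42 and 46 (6%, 60%, 84% and 92%), beside 10 false calls. No gene was called in the other line, where none was changed. camera called 100 of 100 lists of 30 genes shifted by -0.3 in either line, and 1 and 2 of 100 lists that were not shifted. Simulated genes were drawn independently, while estimated correlations within the real lists reached 0.224. The simulation thus cannot show how camera does on lists whose members move together. It also changed far fewer genes than passed in the HIC1 line.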

Results

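Gene expression was measured in 2 lines made from MCF7, an estrogen receptor positive human breast cancer line. In these lines doxycycline switches on an inserted sequence, HIC1 in 1 line and the miR-212/132 cluster in the other. HIC1 encodes a zinc finger transcriptional repressor that is silenced in many tumours, and its gene lies next to that of the miR-212/132 cluster at 17p13.3. Each line was grown with doxycycline (DOX+) or without it (DOX-) for 36 h, and each of the 4 groups had 2 arrays, so n is 2 per group throughout. The number of arrays limits the precision.

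Between 66.6% (miR-212/132 DOX- replicate 1) and 81% (HIC1 DOX+ replicate 1) of the probes were well above background. In the order HIC1 DOX+, HIC1 DOX-, miR-212/132 DOX+ and miR-212/132 DOX-, the shares on replicates 1 and 2 were 81% and 72%, 68.2% and 71%, 72.5% and 68%, and 66.6% and 72%. The median processed signal ran from 96.3 to 130.6 intensity units and no spot was saturated. HIC1 DOX+ replicate 1 had raised low signals, with a lower quartile of 18.2 against 4.58 to 7.93 on the other 7 arrays. The median SD between the 2 arrays of a group was 0.10 log2 in HIC1 DOX+, 0.065 in HIC1 DOX-, 0.068 in miR-212/132 DOX+ and 0.151 in miR-212/132 DOX-. The first principal component held 63.5% of the variance and set the HIC1 DOX+ arrays (scores -96.2 and -85.6) apart from HIC1 DOX- (1.4 and 0.5) and from the 4 arrays of the other line (41.3 to 48.1). The arrays came from 3 slides. Slides 1 and 2 each held 1 HIC1 DOX+ array and both groups of the miR-212/132 line, and slide 3 held both HIC1 DOX- arrays, so that no slide held both groups of the HIC1 line.

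HIC1 itself was induced 280-fold in its line. The probe at 17:1961710-1961769 (hg19) read 6271 and 7238 intensity units in DOX+ against 23.9 and 26.1 in DOX-, a log2 fold change of 8.13 ± 0.14 (adjusted p = 2.57e-05). The rise was 6.52 with normexp from negative control spots. In the miR-212/132 line this probe was not well above background on any array, with 2.66 and 3.08 units in DOX+ and 4.74 and 6.33 in DOX-. The DOX+ arrays of the HIC1 line were at least 679-fold above those of the miR-212/132 line, and even its DOX- arrays were at least 2.42-fold above the uninduced miR-212/132 line. A second HIC1 probe, at 17:1962633-1962692, was not well above background on any array, the induced ones included. The arrays carry no probe for the miR-212 or miR-132 hairpin, so induction of the miRNAs was not measured.

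**Figure D1:**
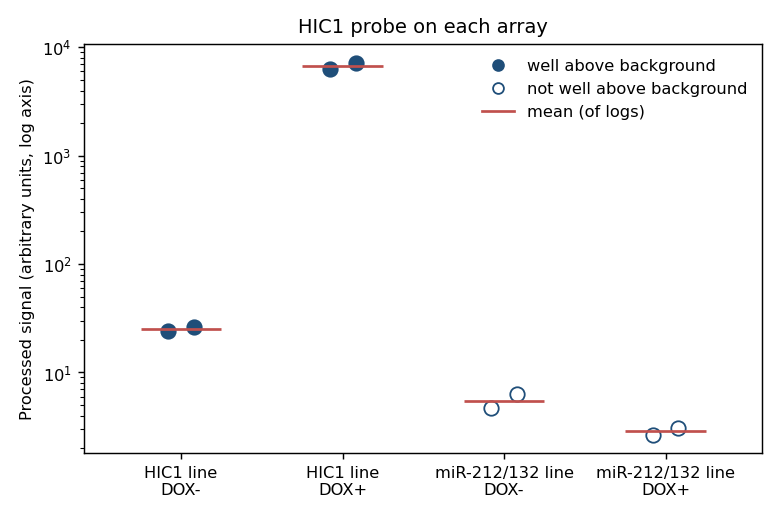
Processed signal of the HIC1 probe (intensity units, log axis) on each of the 8 arrays by group, 1 point per array. The 2 induced HIC1 arrays read 6271 and 7238 units, and the uninduced ones 23.9 and 26.1.

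The first comparison asked what HIC1 does to the transcriptome of these cells. In induced HIC1 cells the listed genes of mitosis (38 of 38), DNA replication (31 of 35), estrogen response (30 of 35, the estrogen receptor gene ESR1 among them) and the ATF4 stress response (24 of 32) fell, as did 9 of 14 metallothionein and zinc transport genes, and 11 of 19 mesenchymal genes rose. Of these list calls, those of mitosis, metallothionein and mesenchymal genes were lost with an estimated correlation (adjusted p = 0.0638, 0.0734 and 0.213). Of 21082 genes tested, 6110 passed, 3345 higher and 2765 lower in DOX+, and 2227 of these changed at least 2-fold (1149 higher, 1078 lower). Among the 3345 higher genes, 372 were not well above background on either DOX- array. COL17A1, a collagen of epithelial anchoring junctions, was at least 68.0-fold higher on its brightest probe (log2 fold change 5.22 on the other), and SPARC, a secreted matrix-binding glycoprotein, at least 52.6-fold higher.

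All 38 measured genes of mitosis and G2/M fell, and all 38 when adjusted over the list alone, with a median log2 fold change of -1.72 (camera adjusted p = 9.71e-29). They included CCNA2, a cyclin of S phase and mitosis (-1.85 ± 0.07), PRC1, a crosslinker of spindle microtubules (-1.78), CDC25C, a phosphatase that activates CDK1 (-1.98), and CDCA8, a subunit of the chromosomal passenger complex (-1.80). The call was lost with adjusted p = 0.0638 with an estimated correlation. Of 35 genes of G1/S and DNA replication 31 fell, 1 rose and 3 did not pass, with 33 lower and 1 higher adjusted over the list alone (median -1.08, adjusted p = 3.19e-19, and adjusted p = 0.0233 with an estimated correlation). Against miR-212/132 DOX- on the same slide, the G1/S median of HIC1 DOX+ was only -0.18 on slide 1 and -0.05 on slide 2, so that most of this fall rested on the HIC1 DOX- arrays of slide 3. The largest falls by p were in PRIM1, the catalytic subunit of primase (-1.81 ± 0.09), GINS2, part of the replicative helicase (-1.50), TYMS, thymidylate synthase (-1.33), and TK1, thymidine kinase (-1.46). The gene that rose was CCNE1, cyclin E1 (0.44), chosen after its value was seen. Of the histone list, which is mainly of replication-dependent genes but also holds the replacement variants H1-0 and H2AZ1, 12 of 17 fell, both over all genes and adjusted over the list alone. Among them were H4C3 (-1.52), H3C10 (-1.22), H1-4 (-1.39) and the variant H2AZ1 (-1.12). Their median was -0.72 (adjusted p = 2.97e-08, but adjusted p = 0.0638 with an estimated correlation).

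Estrogen response genes fell in 30 of 35 cases and 5 did not pass, with 31 lower adjusted over the list alone. Their median was -1.33 over the 34 with a value on every array and -1.28 over all 35 (adjusted p = 7.02e-19, and adjusted p = 0.0151 with an estimated correlation). The 4 with the smallest p were IGFBP4, a binding protein of insulin-like growth factors (-2.69 ± 0.08), MYBL1, a MYB family transcription factor (-2.75), PDZK1, a scaffold protein (-3.34, but -1.23 and -0.97 against miR-212/132 DOX- on the same slides), and CA12, a carbonic anhydrase (-2.36). Several genes were chosen after their values were seen. Among them, ESR1, which encodes the estrogen receptor, fell by 1.38, PGR, the progesterone receptor gene, fell by 1.38, GREB1 fell by 2.34 and TFF1 fell by 0.84 on the log2 scale.

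The ATF4 and integrated stress response list, which holds many amino acid transporters and synthesis enzymes, fell in 24 of 32 cases, with 1 gene higher and 7 not passing, and 25 lower and 1 higher adjusted over the list alone. Its median was -0.81 (adjusted p = 7.84e-12, and adjusted p = 0.0201 with an estimated correlation). SLC7A5, an amino acid transporter, changed by -2.29 ± 0.10, GDF15, a stress-induced cytokine, by -2.21, PCK2, a mitochondrial gluconeogenic enzyme, by -2.12, and ASNS, asparagine synthetase, by -1.41. The gene that rose was NUPR1, a stress-induced chromatin protein (1.23), chosen after its value was seen. Metallothioneins and zinc transport genes fell in 9 of 14 cases, and in 9 adjusted over the list alone, with a median of -2.41 (adjusted p = 2.29e-07, but adjusted p = 0.0734 with an estimated correlation). MT1B (-3.15 ± 0.09), MT1H (-3.04), MT1X (-3.03) and MT2A (-3.26) led them. These metal-binding proteins are close paralogs whose probes may share signal.

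Among mesenchymal and EMT genes 11 of 19 rose, 2 fell and 6 did not pass, with the same counts adjusted over the list alone. The median was 0.42, and the call (adjusted p = 0.0137) was lost with adjusted p = 0.213 with an estimated correlation. FBN1, a microfibril protein (2.81 ± 0.08), FN1, fibronectin (1.68 ± 0.11), COL5A1, a fibrillar collagen (1.22), and SPARC had the smallest p, while the 2 that fell were TGFBI (-0.94) and the EMT transcription factor gene SNAI1 (-1.06), chosen after their values were seen. Cholesterol biosynthesis genes rose in 7 of 24 cases and 1 fell, in both adjustments, with a median of 0.25 (adjusted p = 0.0437, but adjusted p = 0.213 with an estimated correlation). TM7SF2 (0.69), STARD4 (0.76) and DHCR24 (0.76) rose and PMVK (-0.81) fell. Of the 11 measured genes reported in the literature as HIC1 targets, 6 fell, 2 rose and 3 did not pass, with 7 lower and 3 higher adjusted over the list alone (median -0.98, adjusted p = 0.0491, but adjusted p = 0.291 with an estimated correlation). CCND1, cyclin D1, changed by -2.29 ± 0.13, CDKN1A, the CDK inhibitor p21, by -1.29, and ACKR3, a chemokine receptor, by -1.36, whereas CDKN1C, the CDK inhibitor p57, rose by 1.82. Mitochondrial ribosome genes fell in 9 of 44 cases, 8 adjusted over the list alone (MRPL13 -0.57, MRPS18A -0.41, MRPS10 -0.44 and MRPL2 -0.45, median -0.14). Oxidative phosphorylation genes fell in 5 of 50 cases and 1 rose, with 1 lower and none higher adjusted over the list alone (ATP5MC1 -0.54, UQCRQ 0.33, NDUFS2 -0.44 and CYC1 -0.47, median -0.11). Both lists were called (adjusted p = 0.00421 and 0.0382), but gave adjusted p = 0.341 and 0.291 with an estimated correlation.

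The 22 other lists did not pass. Interferon-stimulated genes had 4 higher and 10 lower of 31, with 5 and 12 adjusted over the list alone (median -0.11, adjusted p = 0.0848; ISG20 -0.92, PARP9 1.28, OASL -1.55, IFIH1 -1.45). Epithelial and luminal genes had 3 higher and 6 lower of 33, 5 and 7 adjusted over the list alone (median -0.13, adjusted p = 0.13), led by MUC1, a cell surface mucin (-1.81 ± 0.10), CLDN3 (-0.91), ESRP1 (-1.03) and OVOL1 (-0.58). Lysosome and autophagy genes had 8 higher and 1 lower of 28 in both adjustments (median 0.22, adjusted p = 0.13; GABARAPL1 1.54, CTSS 0.97, CTSL 0.86, TFEB 1.18). NRF2 genes had 4 higher and 9 lower of 24, 6 and 9 adjusted over the list alone (median -0.10, adjusted p = 0.171), with ABCC3, an efflux pump, at -3.39, HMOX1 at -2.12, GPX2 at 2.65 and SLC7A11 at -1.73. Apoptosis regulators had 3 higher and 7 lower of 26, 4 and 8 adjusted over the list alone (adjusted p = 0.171; BIRC3 -1.39, BMF -1.29, BIK -0.75, CFLAR -0.60). Heat shock genes had 7 higher and 3 lower of 18, 9 and 3 adjusted over the list alone (median 0.34, adjusted p = 0.199; SERPINH1 0.93, BAG3 -0.91, HSPB1 -0.86, HSP90AB1 0.58).

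The p53 targets had 4 higher and 6 lower of 29, 4 and 7 adjusted over the list alone (adjusted p = 0.254; GDF15 -2.21, DDB2 -1.18, TP53I3 1.20, CDKN1A -1.29). Neighbours at 17p13.3 had 2 higher, HIC1 among them, and 3 lower of 18, 2 and 4 adjusted over the list alone (adjusted p = 0.363), with SERPINF1 at -1.47, TLCD2 at 0.94 and RTN4RL1 at -1.12. Reported targets of miR-212/132 had 8 higher and 4 lower of 34 in both adjustments (adjusted p = 0.388; CCND1 -2.29, GAB1 0.86, ACHE 1.57, MMP9 -0.92). Unfolded protein response chaperones had 2 higher and 3 lower of 22, 1 and 3 adjusted over the list alone (adjusted p = 0.51; XBP1 -2.09, HERPUD1 -0.66, ERO1B 1.18, DNAJC3 -0.37). Immediate early genes had 9 higher and 10 lower of 32, 10 and 11 adjusted over the list alone (adjusted p = 0.626), with PHLDA1 at 1.34, DUSP6, a phosphatase of ERK, at 1.52, FOS at 1.34 and IER3 at -1.19. Hypoxia and glycolysis genes had 11 higher and 7 lower of 33 in both adjustments (median -0.09, adjusted p = 0.649; SLC2A1 -1.30, VEGFA -0.83, PFKP -0.75, DDIT4 -0.81). NF-kB genes had 5 higher and 5 lower of 20, 6 and 5 adjusted over the list alone (adjusted p = 0.649; BIRC3 -1.39, IER3 -1.19, TNF -0.99, LTB 1.06). Wnt and TCF targets had 6 higher and 5 lower of 19, 8 and 5 adjusted over the list alone (median 0.39, adjusted p = 0.649), with ASCL2 at -1.41, CCND1 at -2.29, LEF1 at 1.37 and SOX9 at least 2.82-fold higher.

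TGF-beta targets had 6 higher and 4 lower of 20, 8 and 5 adjusted over the list alone (median 0.25, adjusted p = 0.746; TGFBI -0.94, CDKN2B -0.88, TGIF1 0.95, BHLHE40 -1.14). Fatty acid synthesis genes had 6 higher and 3 lower of 15, 6 and 4 adjusted over the list alone (median 0.23, adjusted p = 0.862; FADS1 -1.55, ACSL1 -1.01, ACSS2 0.77, ELOVL6 0.51). Ephrins and their receptors had 3 higher and 3 lower of 16, 4 and 3 adjusted over the list alone (median 0.21, adjusted p = 0.862; EPHB2 -0.80, EPHA4 -0.63, EFNB2 1.09, EFNA4 0.59). HIC1 partners and BTB zinc fingers had 4 higher and 2 lower of 16 in both adjustments (adjusted p = 0.679; EZH2 -0.81, TCF7L2 0.74, PHF1 0.60, SMARCA4 0.39). Basal and myoepithelial genes had 6 higher and 6 lower of 16 in both adjustments (median 0.15, adjusted p = 0.998), with LAMB3 at -2.18, EGFR at 1.02, DST at 1.26 and CAV1 at -1.61. No cytosolic ribosomal protein gene passed limma of 50, in either adjustment, and 4 had an unadjusted p under 0.05, all higher (adjusted p = 0.25). Markers of cell types foreign to the line stayed without a call. Immune cell genes had 1 higher (LCP1, 1.44) and 1 lower (CORO1A, -0.45) of 11 in both adjustments (adjusted p = 0.649), and fibroblast and endothelial genes 3 higher of 7 in both adjustments (adjusted p = 0.179; VWF 2.01, EMCN 0.75, COL1A1 0.42).

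Median, mean and test differed in sign for apoptosis regulators (median 0.01, mean -0.17, test down), immediate early genes (0.02, -0.04, down), unfolded protein response chaperones (0.01, -0.08, down), 17p13.3 neighbours (-0.15, 0.25, down), NF-kB genes (0.05, 0.21, down) and fatty acid synthesis (0.23, -0.14, up). With genes dim in 1 group at their bound, the NF-kB median was -0.01. The medians of 8 uncalled lists changed sign under at least 1 scaling of the arrays, namely apoptosis regulators, cytosolic ribosomal proteins, HIC1 partners, immediate early genes, miR-212/132 targets, NF-kB genes, p53 targets and unfolded protein response chaperones.

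The other largest rises were in genes not well above background in DOX-. ITIH2, a hyaluronan-binding protein gene, was at least 11-fold higher, SFTA2 at least 14.1-fold, CACNB4, a calcium channel subunit, at least 12.5-fold, RNF17 at least 9.05-fold, SELENOV at least 8.69-fold, PPY2P at least 7.49-fold and IL36RN, a receptor antagonist of the interleukin 36 family, at least 7.10-fold. RASSF2, a RAS-binding tumour suppressor, rose by 4.81 ± 0.25 (2.02 on its other probe) and KLK1, tissue kallikrein, by 4.73 ± 0.36 with 1 of its 2 DOX- arrays above background. Of genes measured on all 4 arrays and chosen after their values were seen, APOE, a carrier of lipids, rose by 4.27 ± 0.09 and GLI1, a transcription factor of hedgehog signalling, by 3.75. The lowest were EDN2, endothelin 2 (at least 8.68-fold lower), RBM24 (at least 10.7-fold, -2.31 log2 on its other probe), CDH23 (at least 7.46-fold), DKK3, a secreted protein of the dickkopf family (at least 6.31-fold), SIGLEC9 (at least 5.29-fold) and PGLYRP4 (at least 4.87-fold). SLC6A14, an amino acid transporter above background on 1 of 2 DOX+ arrays, changed by -4.54 ± 0.32, CALML5, a calmodulin-like protein of the epidermis, by -4.31 ± 0.18, PLAC1 by -4.28 ± 0.09, TMPRSS3, a membrane serine protease, by -4.23 ± 0.11, ASCL1, a neuroendocrine transcription factor, by -4.14 ± 0.18, and SULT2B1, a sulfotransferase of cholesterol, by -3.69 ± 0.11. DKK3, CDH23 and SIGLEC9 were not well above background on any HIC1 DOX+ or miR-212/132 DOX- array. Their HIC1 DOX+ values against miR-212/132 DOX- on the same slides are thus differences between dim signals. These were 1.11 and -0.68 on slides 1 and 2 for DKK3, 1.48 and -0.66 for CDH23, and 2.18 and -0.68 for SIGLEC9. Slide 1 held the HIC1 DOX+ array with raised low signals. CALML5 was lower by less in this contrast (-1.06 and -1.77). Most or all of these 4 falls thus rested on the HIC1 DOX- arrays of slide 3, the only ones of these groups on which DKK3, CDH23 and SIGLEC9 were well above background. Leaving out single arrays ended 4 of the calls named so far in this paragraph. The log2 fold change of SELENOV was still 5.43 and 4.94 without HIC1 DOX- replicates 1 and 2. That of PPY2P stayed at 4.92 without any 1 miR-212/132 array, since these arrays enter only the spread, its degrees of freedom and the genes tested. SELENOV had adjusted p = 0.0528 and 0.062 without HIC1 DOX- replicates 1 and 2. PPY2P (adjusted p = 0.0459) had 0.115 without HIC1 DOX+ replicate 2, where its log2 fold change was 2.88 against 4.92, 0.148 and 0.175 without HIC1 DOX- replicates 1 and 2, 0.0554 and 0.0638 without miR-212/132 DOX+ replicates 1 and 2, and 0.0791 and 0.073 without miR-212/132 DOX- replicates 1 and 2. It also missed the threshold under quantile normalization (0.125), without a filter on dim probes (0.103), with a replicate block (0.0686) and from the 4 arrays of the line alone (0.0904). CDH23 had 0.0587 without HIC1 DOX+ replicate 2 and 0.0635 without HIC1 DOX- replicate 1, and SIGLEC9 had 0.0627 and 0.1 in the same order. From the 4 arrays of the line alone they had 0.0582 and 0.064.

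The count fell to 3145 without HIC1 DOX- replicate 1 and to 3457 without replicate 2. Under the normexp background correction fixed with the design, whose fitted background was far below 0 on 4 arrays, limma passed none and 358 genes had an unadjusted p under 0.05. The balance of directions moved with scaling and with single arrays. Of the passing genes 54.7% were higher, against 49.3% under quantile normalization, 37.9% with centring on the median and 38.0% in the deposited table, where the median of all genes moved from 0.08 to -0.07. The share was 71.2% (5144 of 7220) without HIC1 DOX+ replicate 2 and 49.0% (2255 of 4606) without HIC1 DOX+ replicate 1. Leaving out an array also loosened the filter, since a probe then entered if well above background on the 1 array left in that group. Without HIC1 DOX+ replicate 2, 24222 genes were tested, against 21242 without replicate 1. Part of the higher share without replicate 2 may thus come from genes that entered on replicate 1 alone. A fit with the slide as a fixed term could not be had, since no slide held both groups. Against miR-212/132 DOX- on the same slide, 5644 of 6110 passing genes moved in the direction called on slide 1 and 5747 of 6107 on slide 2, with median signed shifts of 0.87 and 0.845 log2. In this same-slide contrast the medians on slides 1 and 2 were -1.75 and -1.65 for G2/M, -1.23 and -1.24 for estrogen response, -1.10 and -1.01 for ATF4 genes, -0.77 and -0.88 for histones, and -2.38 and -2.60 for metallothioneins. They were 1.33 and 1.26 for mesenchymal genes, 0.09 and 0.18 for cholesterol genes, -0.50 and -0.67 for HIC1 targets, -0.35 and -0.16 for mitochondrial ribosome, -0.18 and -0.16 for oxidative phosphorylation, and -0.18 and -0.05 for G1/S.

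The list of HIC1 targets lost its call under quantile normalization (adjusted p = 0.0504), with median centring (0.0926), in the deposited table (0.0919), with the slide as a random block (0.0537), with a replicate block (0.0576) and from the 4 arrays of the line alone (0.0572). It also lost it without HIC1 DOX- replicate 1 (0.0951), HIC1 DOX- replicate 2 (0.056) or miR-212/132 DOX+ replicate 1 (0.0515). Cholesterol genes lost theirs with median centring (0.13), in the deposited table (0.133) and with the slide as a random block (0.188), and without HIC1 DOX+ replicate 2 (0.469), HIC1 DOX- replicate 2 (0.0665) or miR-212/132 DOX+ replicate 1 (0.0515). Oxidative phosphorylation lost its call under quantile normalization (0.591), with the slide as a random block (0.311), over probes well above background on all 8 arrays (0.0748), with normexp from negative control spots (0.0657), and without HIC1 DOX+ replicate 1 (0.116) or HIC1 DOX- replicate 1 (0.156). For mitochondrial ribosome genes this happened under quantile normalization (0.232), with the slide as a random block (0.152) and without HIC1 DOX+ replicate 1 (0.0632). The mesenchymal median was 0.79 without HIC1 DOX+ replicate 2. Over bright probes without HIC1 DOX+ replicate 1, mesenchymal (0.109), mitochondrial ribosome (0.109) and oxidative phosphorylation (0.181) genes did not pass.

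**Figure D2:**
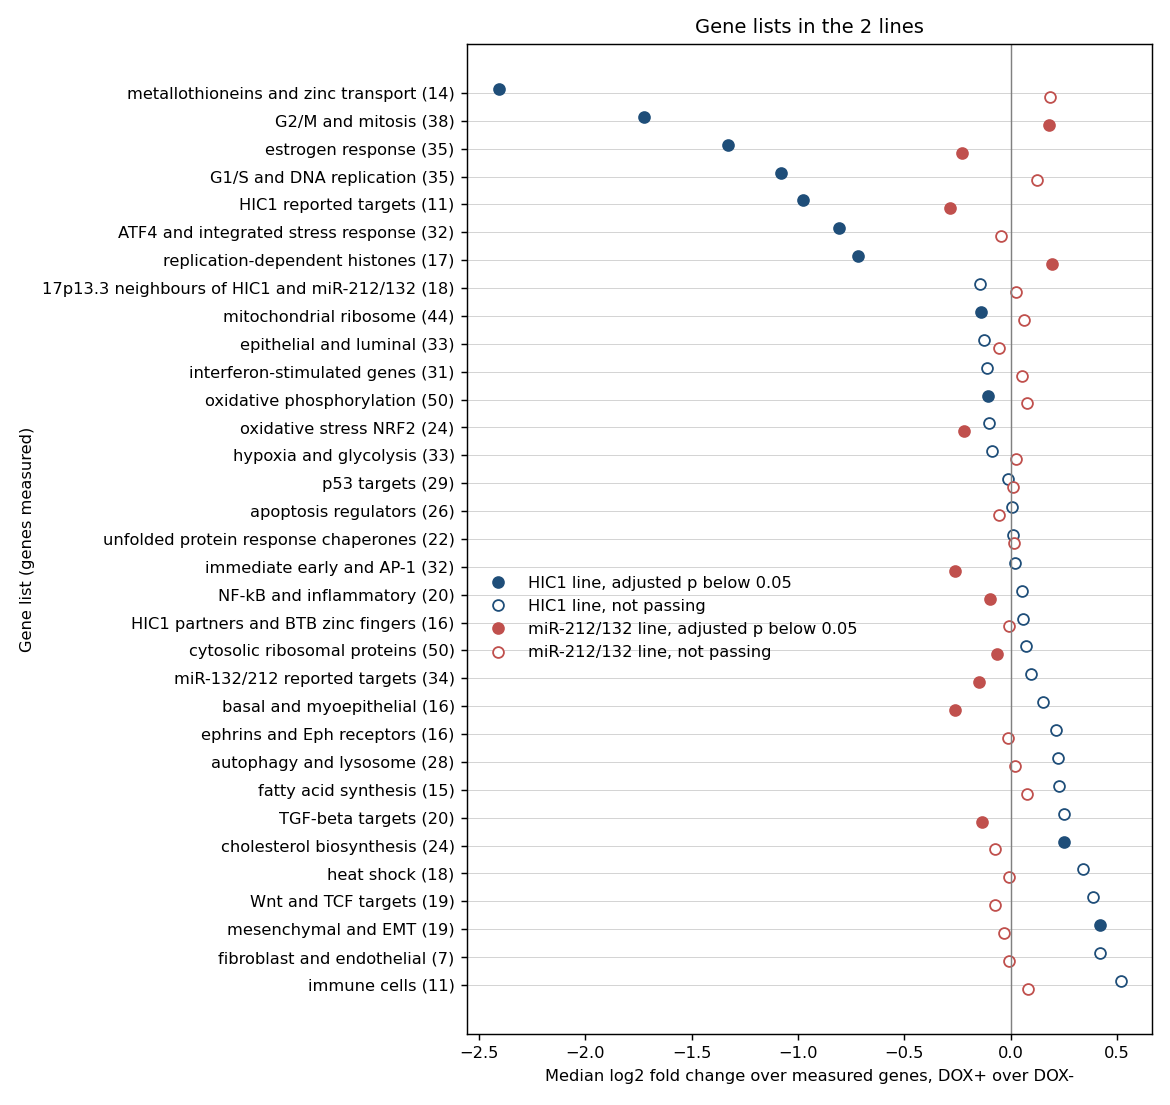
Median log2 fold change (DOX+ over DOX-) of the genes with a value on every array in each of the 33 lists in both lines, filled where camera passed at the preset correlation. G2/M genes lay at -1.72 in the HIC1 line and 0.18 in the miR-212/132 line, and estrogen response genes at -1.33 and -0.23.

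The second comparison asked what the miR-212/132 cluster does in the same cell background. In the fit of all 8 arrays 101 genes passed, 15 higher and 86 lower, and 48 changed at least 2-fold (7 higher, 41 lower), while 2903 had an unadjusted p under 0.05. The number moved with each array left out, and no gene passed as lower when any 1 of 6 arrays was left out. The HIC1 arrays among these enter no fold change of this line. Leaving them out changed only the spread, its degrees of freedom and the genes tested, and not the direction of a change. The clearest change was a rise of GALNT16, an enzyme that starts mucin-type O-glycosylation, by 3.38 ± 0.11 (adjusted p = 0.00154). NAP1L1, a histone chaperone, fell by 1.98 ± 0.12 (adjusted p = 0.0147), and RASD1, a dexamethasone-induced RAS-like GTPase, by 1.69 ± 0.12 (adjusted p = 0.0267). GALNT16 and RASD1 moved the same way with doxycycline in the HIC1 line. Of the 101 genes, 38 were called lower and 8 higher in both lines. For such genes an effect of the miRNAs cannot be told apart from one of doxycycline.

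Among the other higher genes, AGPAT4, a lysophospholipid acyltransferase, was at least 3.61-fold higher (adjusted p = 0.00468). BRWD3 rose by 1.30, ACE2, the angiotensin converting enzyme 2, by 1.20, IMPDH1, an enzyme of guanine nucleotide synthesis, by 1.05, CECR2 by 0.86, SGK1, a serum and glucocorticoid regulated kinase, by 0.82, IGFLR1 by 0.81, GNG7 by 0.78 and RDM1 by 0.77. Among the lower genes, SLC6A19, an amino acid transporter, changed by -1.65, AKR1B10, an aldo-keto reductase above background on 1 of 2 DOX+ arrays, by -1.56, ASCL1 by -1.43, KRT37 by -1.38, TIMP3, an inhibitor of metalloproteases, by -1.33, CUL4B, a ubiquitin ligase scaffold, by -1.26 and CALCR, the calcitonin receptor gene, by -1.25. The other CUL4B probe lay at -0.54 and did not pass. RHOH and RAB7B passed as lower, but were above background on 1 of 2 DOX- arrays and on no DOX+ array, so that no fold is given, and another RAB7B probe lay at 0.65. ISM1 passed, yet it was not well above background in either group, so that no fold is given.

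Of 34 measured genes reported as targets of miR-212/132, 1 fell, none rose and 33 did not pass, with 4 lower adjusted over the list alone. Their median was -0.15 (-0.20 and -0.14 within slides 1 and 2, adjusted p = 7.27e-05, and 0.000178 with the slide as a fixed block, but adjusted p = 0.145 with an estimated correlation). RASA1, a GTPase activating protein of RAS, fell by 1.01 ± 0.12, and values of RB1 (-0.62), FOXO1 (-0.44) and MAPK1 (-0.49) did not pass. Estrogen response genes had 1 lower of 35, with 9 lower and 1 higher adjusted over the list alone (median -0.23, or -0.22 over all 35, within slides -0.20 and -0.23, adjusted p = 2.11e-08, blocked 1.64e-08, but adjusted p = 0.0675 with an estimated correlation). IGFBP5, a binding protein of insulin-like growth factors, changed by -1.21 ± 0.12 (adjusted p = 0.0371), beside TFF3 (-0.76), RET (-1.24) and AREG (-1.28), which did not pass. Immediate early genes had 1 lower of 32, EGR1 (-0.86 ± 0.11), and 9 lower adjusted over the list alone (median -0.26, within slides -0.28 and -0.27, adjusted p = 1.38e-07, blocked 4.17e-08, but adjusted p = 0.166 with an estimated correlation). KLF2 (-0.86), KLF6 (-0.51) and CCN1 (-0.56) did not pass.

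NRF2 genes had 2 lower of 24, ABCC3 (-1.23 ± 0.09) and AKR1B10, and 7 lower adjusted over the list alone (median -0.22, within slides -0.25 and -0.09, adjusted p = 0.00034, blocked 0.000622, but adjusted p = 0.166 with an estimated correlation). NF-kB genes had 2 lower of 20, SOD2 (-0.68) and LTB (-1.16), and 3 lower adjusted over the list alone (median -0.10, within slides -0.14 and -0.18, adjusted p = 0.00532, blocked 0.00505, but adjusted p = 0.203 with an estimated correlation). TGF-beta targets had 1 lower of 20, TGFBI (-0.86), and 5 lower and 1 higher adjusted over the list alone (median -0.14, within slides -0.05 and -0.26, adjusted p = 0.0125, blocked 0.0111, but adjusted p = 0.166 with an estimated correlation). Basal genes had none passing limma of 16, 6 lower at an unadjusted p under 0.05 and 5 lower adjusted over the list alone (median -0.26, within slides -0.37 and -0.26, adjusted p = 0.000147, blocked 0.000246, but adjusted p = 0.145 with an estimated correlation), with KRT17 at -0.88 and MYLK at -0.67. The reported HIC1 targets had none passing of 11, 4 lower at an unadjusted p under 0.05 and 1 lower adjusted over the list alone (median -0.28, within slides -0.27 and -0.35, adjusted p = 0.0117, blocked 0.0103, but adjusted p = 0.209 with an estimated correlation). Cytosolic ribosomal protein genes had none passing of 50 in either adjustment and none at an unadjusted p under 0.05 (median -0.07, within slides -0.07 and -0.05, adjusted p = 0.00331, blocked 0.00473, but adjusted p = 0.337 with an estimated correlation).

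The median was above 0 in a pair of called lists. G2/M genes had none passing limma of 38 in either adjustment and 13 higher at an unadjusted p under 0.05 (median 0.18, within slides 0.10 and 0.27, adjusted p = 7.27e-05, blocked 0.000178, but adjusted p = 0.308 with an estimated correlation), with PLK1 and FOXM1 both at 0.46. Histones had none passing of 17, 7 higher at an unadjusted p under 0.05 and 1 higher adjusted over the list alone, H4C3 (0.43), chosen after its value was seen (median 0.19, within slides 0.20 and 0.17, adjusted p = 0.00034, blocked 0.000708, but adjusted p = 0.166 with an estimated correlation). The 22 other lists did not pass, and 3 of them held 1 passing gene, which were TGFBI among mesenchymal genes, VWF (-0.77) among fibroblast and endothelial genes, and NDUFB10 (-0.78) in oxidative phosphorylation. Their smallest adjusted p values were 0.0607 for cholesterol biosynthesis (median -0.07), 0.0812 for epithelial genes (-0.06) and 0.0833 for G1/S (0.12). Median, mean and test differed in sign for 17p13.3 neighbours (0.02, -0.02, down), hypoxia and glycolysis (0.03, -0.04, down) and immune cells (0.08, 0.02, down).

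The number of genes called in this line moved with single arrays, also with HIC1 arrays, which enter no fold change of this line. The count was 2 without HIC1 DOX+ replicate 1, 1 without HIC1 DOX+ replicate 2, 3 without either HIC1 DOX- array, 3 without miR-212/132 DOX+ replicate 1 and 13 without replicate 2, and in each of these 6 settings every passing gene was higher. It was 679 without miR-212/132 DOX- replicate 1, which held 96 of the 101 in the same direction (236 higher, 443 lower), and 15 without replicate 2 (3 higher, 12 lower). The 4 arrays of this line alone gave 3 genes and no filter on dim probes gave 2, all higher. It was 5 with the slide as a fixed block and 8 with the slide as a random block. With a replicate block limma passed none, and 2519 genes had an unadjusted p under 0.05. GALNT16 passed in every setting run except that block and the normexp correction fixed with the design. AGPAT4 also lost its call without HIC1 DOX+ replicate 2 (0.106) and without miR-212/132 DOX+ replicate 1 (0.0632). Leaving out miR-212/132 DOX- replicate 1 left 7 lists called and ended the calls of G2/M (0.251, median 0.07), NF-kB genes (0.132), TGF-beta targets (0.344) and HIC1 targets (0.0928). Leaving out miR-212/132 DOX- replicate 2 gave 18 lists and moved the medians of TGF-beta targets to -0.23 and of NRF2 genes to -0.11. The TGF-beta median was -0.08 without miR-212/132 DOX+ replicate 2. Quantile normalization ended the call of cytosolic ribosomal protein genes (0.276), and TGF-beta targets did not pass over probes well above background on all 8 arrays (0.0609) or from the 4 arrays of the line alone (0.0808). With fry, 16 lists passed, but not G2/M (0.0648) or cytosolic ribosomal proteins (0.0541). Within slides 1 and 2 the median sizes of the 101 changes were 0.983 and 0.903, values that re-pair the 4 arrays behind the calls.

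The third comparison set the lines against each other, each serving as the doxycycline control of the other. Both HIC1 DOX- arrays lay alone on slide 3, so that any effect of that slide enters this difference. The response to doxycycline differed for 3771 genes, 1878 with a higher and 1893 with a lower log2 response in the HIC1 line. The fitted difference of HIC1 itself was 9.07, which is no bound since its probe was not above background in the miR-212/132 line. UBD, a ubiquitin-like modifier, differed by 4.65 ± 0.17, while PLAC1 (-3.91 ± 0.13), CALML5 (-4.15 ± 0.26) and MT2A (-3.58 ± 0.16) were lower in the HIC1 line's response. For CALML5, HIC1 DOX+ minus miR-212/132 DOX- on the same slide was only -1.06 on slide 1 and -1.77 on slide 2. The list test separated the lines for G2/M (median difference -1.87, adjusted p = 2.68e-30), G1/S (-1.24, 9.52e-18), estrogen response (-0.90, 9.74e-13) and ATF4 genes (-0.76, 2.73e-10), but G2/M had adjusted p = 0.0581 with an estimated correlation. The other 3 passed with an estimated correlation as well (adjusted p = 0.0271, 0.0266 and 0.0266). For G1/S, however, the median of HIC1 DOX+ minus miR-212/132 DOX- was only -0.18 on slide 1 and -0.05 on slide 2. Most of the G1/S difference thus rested on the HIC1 DOX- arrays of slide 3. G2/M had 37 of 38 genes with a lower response in the HIC1 line (38 adjusted over the list alone), G1/S 29 of 35 lower and 1 higher (31 and 1), estrogen response 20 of 35 lower (21, with 2 higher) and ATF4 genes 21 of 32 lower and 1 higher (24 and 1).

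The other 8 list calls did not hold with an estimated correlation, though fry, which tests each list on its own, passed them as well. Histones had 12 of 17 genes lower in the HIC1 line's response (15 adjusted over the list alone, median difference -0.90, adjusted p = 9.53e-10, but adjusted p = 0.0564 with an estimated correlation), and metallothioneins 8 of 14 (8, -2.57, 2.69e-07, but adjusted p = 0.0747 with an estimated correlation). Most members of the other 6 lists did not pass. Mitochondrial ribosome had 5 lower of 44 (5, -0.21, 0.002, but adjusted p = 0.368 with an estimated correlation), and oxidative phosphorylation 3 lower and 1 higher of 50 (1 and 1, -0.15, 0.00724, but adjusted p = 0.18 with an estimated correlation). Mesenchymal genes had 8 higher and 1 lower of 19 (9 and 1, 0.75, 0.00282, but adjusted p = 0.132 with an estimated correlation), and miR-212/132 targets 10 higher and 2 lower of 34 (14 and 4, 0.48, 0.00599, but adjusted p = 0.151 with an estimated correlation). Cholesterol genes had 4 higher and 1 lower of 24 (10 and 1, 0.40, 0.00599, but adjusted p = 0.119 with an estimated correlation). Of 50 cytosolic ribosomal protein genes none passed limma in either adjustment, and 7 had an unadjusted p under 0.05, all higher (0.14, 0.0179, but adjusted p = 0.522 with an estimated correlation).

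The count of genes was 1694 without HIC1 DOX- replicate 1, 1840 without HIC1 DOX- replicate 2, 1889 without miR-212/132 DOX+ replicate 1 and 1676 without miR-212/132 DOX+ replicate 2, and 49.8% of them were higher in the HIC1 line against 39.2% with median centring, 38.8% in the deposited table and 68.7% without HIC1 DOX+ replicate 2. Without HIC1 DOX+ replicate 2 the calls of miR-212/132 targets (adjusted p = 0.218), cholesterol genes (0.19) and cytosolic ribosomal protein genes (0.245) were lost. Without that array probes could enter on HIC1 DOX+ replicate 1 alone, and 24222 genes were tested. Its share of higher genes is thus not one of the same genes. With the slide as a random block, miR-212/132 targets (0.0538), oxidative phosphorylation (0.148) and cytosolic ribosomal protein genes (0.158) did not pass. Oxidative phosphorylation lost its call under quantile normalization (0.0796), and so did cytosolic ribosomal protein genes (0.0691). The latter also lost theirs with normexp from negative control spots (0.138), with median centring (0.268), in the deposited table (0.258), and without HIC1 DOX+ replicate 1 (0.0603) or HIC1 DOX- replicate 2 (0.0628).

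Across all 21082 genes the responses of the lines correlated weakly, with Pearson's r of 0.10 and Spearman's rho of 0.045 (covariance 0.024, 0.04 to 0.104 for r from single pairs of arrays). Genes are not independent replicates, so no p is given. Of the 101 genes called in the miR-212/132 line, 38 were lower in both lines against 11.3 for independent calls, and 8 were higher in both against 2.4. Both calls use the same estimate of a gene's spread, from all 8 arrays. Genes with a small estimate are thus called more easily in both lines, and calls would not be independent even without a shared response. Genes higher in both included the leading pair of the miR-212/132 line, GALNT16 (2.68 ± 0.11 in the HIC1 line) and AGPAT4 (4.43 ± 0.11, with 1 HIC1 DOX- array above background), and also SGK1 (1.59), DYRK3 (1.67) and BRWD3 (1.66). Genes lower in both included IGFBP5 (-2.14 in the HIC1 line), RASD1 (-1.98), TIMP3 (-1.70), ABCC3 (-3.39), ASCL1 (-4.14) and CALCR (-3.09). A further 19 genes were higher in the HIC1 line and lower in the other (13.6 for independent calls), and 1, RDM1, the reverse (2.0).

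**Figure D3:**
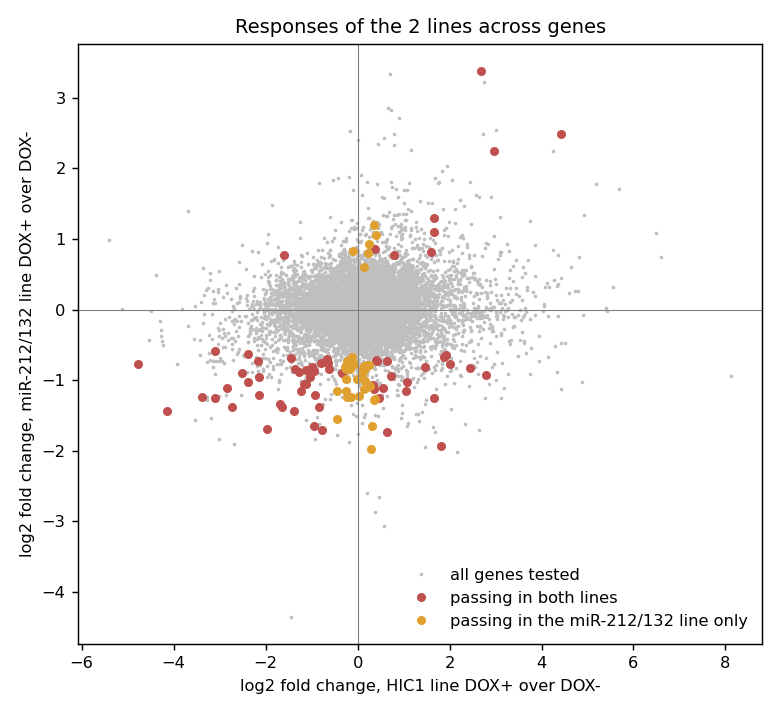
Log2 fold change with doxycycline in the HIC1 line (x axis) against that in the miR-212/132 line (y axis), 1 point per gene, coloured by the line in which the gene passed. The responses correlate with r of 0.10, and GALNT16 lies at 2.68 and 3.38.

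The fourth comparison set the uninduced lines, which lay on separate slides, against each other. It shows differences without induction that may come from line or slide. Of the lists fixed in advance, G1/S and DNA replication genes were higher in the uninduced HIC1 line (28 of 35), with adjusted p = 0.0695 with an estimated correlation. The NF-kB (7 of 20 lower), ATF4 (10 of 32) and lysosome (8 of 28) lists were called lower, with most members not passing and adjusted p = 0.32 with an estimated correlation for each. In all 4005 genes passed, 2337 higher and 1668 lower in the HIC1 line, of which 953 differed at least 2-fold (652 higher, 301 lower). KLK11 and KLK12, kallikrein proteases, were higher by 5.14 ± 0.14 (1 of 2 miR-212/132 DOX- arrays above background) and 3.83 ± 0.11, and FOS, an immediate early gene chosen after its value was seen, by 2.58. Among the lowest were TMTC1 (-4.17 ± 0.31), BRINP3 (-3.33 ± 0.12), LAMP3, a lysosomal membrane protein (-3.15 ± 0.15), and CSTA, a cysteine protease inhibitor (-3.00 ± 0.10). The other CSTA probe lay at -1.73 and did not pass.

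G1/S genes were higher in 28 of 35 cases, none was lower and 7 did not pass, with 33 higher adjusted over the list alone (median 0.90, adjusted p = 5.92e-19, but adjusted p = 0.0695 with an estimated correlation). E2F2 (1.72 ± 0.10), ORC1 (1.71), CDC6 (1.30) and GINS2 (1.15), which encode an E2F transcription factor and parts of the replication licensing machinery, had the smallest p. G2/M genes had 2 higher and 1 lower of 38, 1 and 1 adjusted over the list alone (median -0.02, 0.01 under quantile normalization, adjusted p = 0.763). NF-kB genes had 7 lower and 1 higher of 20, 9 and 2 adjusted over the list alone (median -0.30, -0.28 with genes dim in 1 group at their bound, adjusted p = 0.00911, but adjusted p = 0.32 with an estimated correlation), with BIRC3, an inhibitor of apoptosis, at -1.84, IER3 at -0.76, ICAM1 at -0.73 and LTB at 1.41. ATF4 genes had 10 lower and 3 higher of 32 in both adjustments (median -0.20, adjusted p = 0.0124, but adjusted p = 0.32 with an estimated correlation), with NUPR1 at -1.45, SLC7A5 at -1.14, DDIT3 at -0.97 and SLC3A2 at -0.85. Lysosome and autophagy genes had 8 lower and 1 higher of 28, 13 and 2 adjusted over the list alone (median -0.29, adjusted p = 0.0344, but adjusted p = 0.32 with an estimated correlation), with the cathepsin genes CTSS (-1.11) and CTSL (-1.09), ATG16L1 (-0.84) and NEU1 (-0.44). Oxidative phosphorylation genes had 7 lower of 50 and none adjusted over the list alone (median -0.10, adjusted p = 0.0344, but adjusted p = 0.452 with an estimated correlation). Mitochondrial ribosome genes had 3 lower and 1 higher of 44, 2 and none adjusted over the list alone (median -0.14, adjusted p = 0.0477, but adjusted p = 0.536 with an estimated correlation). The 27 other lists did not pass.

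Other genes well above background on both HIC1 DOX- arrays and on no uninduced miR-212/132 array were MMP1, an interstitial collagenase (at least 7.45-fold higher), CDH23 (at least 6.90-fold), DKK3 (at least 5.84-fold), ANTXR2 (at least 5.07-fold), SIGLEC9 (at least 4.90-fold), NRAP (at least 4.75-fold), ZNF717 (at least 3.77-fold), GJB5 (at least 2.93-fold) and GLRB (at least 2.88-fold), and GNAI1, dim on 1 of them, was higher by 3.83 ± 0.27. The reverse held for GLDC, glycine decarboxylase (at least 7.23-fold lower), ZNF521 (at least 5.78-fold) and HDAC9 (at least 2.07-fold). Lower by 2.79 to 3.08 were SLC28A3 (-3.08), CLGN (-2.94), HGD (-2.84), ANKRD29 (-2.80) and CDH18 (-2.79). Under normexp with negative control spots NRAP (0.62, adjusted p = 0.09), ZNF717 (0.45, 0.0673), GJB5 (0.39, 0.163), GLRB (0.43, 0.097) and HDAC9 (-0.12, 0.776) did not pass. The other HDAC9 probe lay at -0.66, a smaller fold than that bound, and did not pass. The other 2 ANTXR2 probes lay at 0.01 and 0.26, and the call of MMP1 was lost in the deposited table (adjusted p = 0.1). Leaving out single arrays ended 4 of these calls as well. CDH23 had adjusted p = 0.0768 without HIC1 DOX- replicate 1, 0.0504 without miR-212/132 DOX- replicate 1, 0.0728 without replicate 2 and 0.0515 without a filter on dim probes. SIGLEC9 had 0.0901 without HIC1 DOX- replicate 1 and 0.0736 without miR-212/132 DOX- replicate 2, and ANTXR2 had 0.0579 without HIC1 DOX- replicate 1. HGD had 0.0839 and 0.0751 without HIC1 DOX- replicates 1 and 2, and 0.0598 without miR-212/132 DOX- replicate 2.

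Both HIC1 DOX- arrays lay on a slide of their own, so that slide and line cannot be told apart in this comparison. The count of genes was 2665 without HIC1 DOX+ replicate 2, 1039 and 1308 without HIC1 DOX- replicates 1 and 2, and 2505 and 2250 without miR-212/132 DOX+ replicates 1 and 2. The share of higher genes fell from 58.4% to 46.7% with median centring and 46.9% in the deposited table. The ATF4 call was lost under quantile normalization (adjusted p = 0.0846) and without miR-212/132 DOX- replicate 1 (0.0573), and the NF-kB call without that array (0.06). The lysosome call was lost under quantile normalization (0.0986) and without HIC1 DOX+ replicate 1 (0.0572), HIC1 DOX- replicate 2 (0.128) or miR-212/132 DOX- replicate 1 (0.135, median -0.16). Those of oxidative phosphorylation (0.291) and mitochondrial ribosome (0.291) were also lost under quantile normalization. The first was lost without HIC1 DOX+ replicate 1 (0.0572), HIC1 DOX- replicate 2 (0.137, median -0.05) or miR-212/132 DOX- replicate 1 (0.135). The second was lost without HIC1 DOX+ replicate 1 (0.0653), HIC1 DOX- replicate 2 (0.149), miR-212/132 DOX+ replicate 1 (0.0539), replicate 2 (0.0523) or miR-212/132 DOX- replicate 2 (0.225, median -0.07). Over probes well above background on all 8 arrays, lysosome (0.0568), oxidative phosphorylation (0.0642) and mitochondrial ribosome (0.08) genes did not pass, nor did they from the 4 arrays compared alone (0.0821, 0.0821 and 0.0957). Oxidative phosphorylation and mitochondrial ribosome also did not pass with the slide as a random block (0.121 and 0.127) or with normexp from negative control spots (0.146 for both).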

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

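The tests of scaling, of the estrogen list's difference between the lines, of the G1/S list within slides, of dim genes called higher without 1 array, and of the correlation over all members were chosen only after the result was seen. A test of the difference between the lines picked out the genes and lists of the next paragraph, and the weighed patterns go beyond these.

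The response differed for 3771 genes, and for the lists of G2/M (median log2 difference -1.87, HIC1 line minus miR-212/132 line), G1/S (-1.24), estrogen response (-0.9), histones (-0.9), ATF4 genes (-0.76), metallothioneins (-2.57), mitochondrial ribosome (-0.21), oxidative phosphorylation (-0.15), mesenchymal genes (0.75), miR-212/132 targets (0.48), cholesterol biosynthesis (0.4) and cytosolic ribosomal proteins (0.14). Of these 12 lists, 3 passed with an estimated correlation, namely G1/S, estrogen response and ATF4 genes, and the other 9 did not (adjusted p = 0.0581 for G2/M, 0.0564 for histones, 0.0747 for metallothioneins and 0.119 to 0.522 for the rest, with an estimated correlation). Most members did not pass in 6 of the lists, namely mitochondrial ribosome, oxidative phosphorylation, mesenchymal genes, miR-212/132 targets, cholesterol biosynthesis and cytosolic ribosomal proteins. The genes with the highest log2 difference were HIC1 (9.07), CACNB4 (5.91), COL17A1 (5.85), SPARC (5.42), RNF17 (5.38), SFTA2 (5.24), IL36RN (4.98), SOD3 (4.9), FLT1 (4.82), MEF2C (4.67), UBD (4.65) and KLK1 (4.47). Those with the lowest were CDH23 (-4.87), DKK3 (-4.47), CALML5 (-4.15), SLC6A14 (-4.11), EDN2 (-4.01), RBM24 (-3.99), DAPL1 (-3.96), PLAC1 (-3.91), PGLYRP4 (-3.81), TMPRSS3 (-3.72), S100A12 (-3.64) and MT2A (-3.58). For 17 of these 24 genes a line's response rested on signals not well above background, so that the size of the difference is a fitted value and no bound. The call of CDH23 was lost without HIC1 DOX+ replicate 2 (adjusted p = 0.102), HIC1 DOX- replicate 1 (0.109), miR-212/132 DOX+ replicates 1 and 2 (0.146 and 0.116) or miR-212/132 DOX- replicates 1 and 2 (0.0888 and 0.114), without a filter on dim probes (0.114) and with the slide as a random block (0.0501). DKK3 lost its call without miR-212/132 DOX+ replicate 2 (0.0649) and with a replicate block (0.0661), and RBM24 without HIC1 DOX- replicates 1 and 2 (0.0584 and 0.0538) or miR-212/132 DOX+ replicate 2 (0.0641). Under normexp with negative control spots the differences of MEF2C (0.53, adjusted p = 0.312), CDH23 (-1.33, 0.102), EDN2 (-0.61, 0.0748) and PGLYRP4 (-0.44, 0.257) did not pass.

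The response of the HIC1 line took in 6110 genes, with 372 of the higher ones dim without doxycycline. A difference between slides as the whole cause was argued against by HIC1 DOX+ minus miR-212/132 DOX- on the same slide, where the called genes kept a median signed shift of 0.845 log2 on slide 2 and 0.87 on slide 1, but for the G1/S list that contrast was -0.053 and -0.184, so that slide 3 and the uninduced line cannot be told apart as the source of its fall. Raised low signals on HIC1 DOX+ replicate 1 as the whole cause were argued against by 66.6% of calls (4072 of 6110) kept in the same direction among 4606 genes passing without that array. Without it 339 dim genes were called higher, 91.1% of the number with it and 257 of them the same genes, while 2516 were called from replicate 1 without replicate 2, so that part of such calls may come from that array. In either fit a dim gene could enter on the 1 HIC1 DOX+ array left, a looser filter than in the main fit. The counts of dim genes may thus also take in genes not tested there. A response to induced HIC1 is the candidate explanation that the design names, as a hypothesis, and doxycycline acting differently in this line or a culture effect shared by both DOX+ cultures was not tested and stays open.

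The estrogen response list was called lower with doxycycline in both lines. In the HIC1 line 30 of its 35 genes passed, and in the other 1 of 35. The immediate early list was called lower in the miR-212/132 line (1 of 32). In that line both calls were lost (adjusted p = 0.0675 and 0.166 with an estimated correlation). For estrogen response the estimate (-0.01) was below the preset 0.01, so members moving together cannot account for that loss. The immediate early list had a median of 0.02 and no call in the HIC1 line. It had no called difference between the lines (adjusted p = 0.2). Scaling of the arrays was argued against by a median of -0.215 for both lists together in the miR-212/132 line under quantile normalization, and -0.687 in the HIC1 line, over 66 genes. In the HIC1 line the immediate early genes went both ways (9 higher and 10 lower of 32). The pooled value there says nothing about them. An effect of doxycycline alone on both lines stays open, with r = 0.285 across all members between the lines (rho of 0.194 for estrogen response and 0.052 for immediate early genes). The value planned for it, r = 0.707 over 18 members, leaves out genes called in 1 line only, which favours members that go together, and rested on IGFBP5 (0.442 without it), so that it decides nothing. Doxycycline alone, acting alike in both lines, was argued against as the whole cause of the estrogen list's fall in the HIC1 line, which went beyond that in the other line by a median of -0.9 (adjusted p = 0.0266 with an estimated correlation, 34 genes).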

How the results depend on the processing

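Normexp with negative control spots, bright probes without HIC1 DOX+ replicate 1, and the searches of probes for seed sites, including the longer site and the 5p seeds, were chosen only after the data were seen. Of the values of named genes under the other settings, 449 of 492 in the HIC1 line, 156 of 497 in the miR-212/132 line, 422 of 463 for the difference and 449 of 489 between the uninduced lines kept their direction and call. For lists these were 227 of 264, 240 of 264, 239 of 264 and 98 of 126. Where leaving out an array left a group with 1, that array was assumed to vary like the other groups. A seed search in 3′ untranslated regions was not run for want of transcript sequences, and the slide as a fixed term was not estimable for the HIC1 line. Deviations from the group mean, paired by replicate number, correlated across genes with r of -0.032 in the HIC1 line and 0.015 in the other, and between the lines with 0.159 for HIC1 DOX+ and miR-212/132 DOX+, which shared slides, 0.139 for HIC1 DOX+ and miR-212/132 DOX-, and 0.027 and 0.041 for HIC1 DOX- with these. Signal over background limited the low genes, so that a gene dim in 1 group has only a bound on its fold. Except where a cause is named, the cause was not tested.

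Leaving out 1 array at a time gave 3145 to 7365 genes for the HIC1 line, 1 to 679 for the miR-212/132 line, 1676 to 5158 for the difference and 1039 to 5325 for the uninduced lines. It gave 9 to 15 lists for the HIC1 line, 7 to 18 for the miR-212/132 line and 12 to 14 for the difference, a HIC1 rise of 8.089 to 8.168, a seed site value (median log2 fold change of genes with a site minus that of the others, -0.068 in the main setting) of -0.117 to -0.056 and a correlation between the responses of 0.036 to 0.104. In the miR-212/132 line, leaving out a HIC1 array changed no fold of a probe, only the spread, its degrees of freedom and the genes tested.

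Normexp as fixed with the design passed 0 genes in each of the 4 comparisons, 17 lists in the HIC1 line, a HIC1 rise of 3.747 and a correlation of -0.719. Its fitted background means were -618.2, -2157, -1574 and -139.6 units on HIC1 DOX+ replicates 1 and 2, HIC1 DOX- replicate 1 and miR-212/132 DOX- replicate 1, against -5.154 to -0.9104 on the others, which added unequal amounts to the arrays. Unadjusted p values under 0.05 numbered 358, 39, 193 and 471. Signs reversed for EDN2 (1.014), SLC6A14 (0.266), DKK3 (0.864), CDH23 (1.228), RBM24 (0.933), PGLYRP4 (1.223), SIGLEC9 (1.28) and cholesterol genes (-0.05) in the HIC1 line, and for AGPAT4 (-0.146), ACE2 (-0.172) and cytosolic ribosomal proteins (0.033) in the other. They reversed for the differences of CDH23 (1.887), DKK3 (1.559), SLC6A14 (0.726), EDN2 (1.724), RBM24 (1.325), DAPL1 (1.695), PLAC1 (0.098), PGLYRP4 (1.831), cholesterol genes (-0.04) and cytosolic ribosomal proteins (-0.474), and between the uninduced lines for ZNF521 (0.243), GLDC (0.24), HDAC9 (0.609) and NF-kB genes (0.246). Normexp with negative control spots kept 4222 of the 6110 calls of the HIC1 line, 65 of 101, 2374 of 3771 and 2408 of 4005, with a HIC1 rise of 6.52, a seed site value of -0.047, a correlation of 0.06, and ISM1 at 0.044 in place of a fall.

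In the miR-212/132 line the count was 32 under quantile normalization, 20 with median centring, 14 in the deposited table, 57 with outlier spots kept, 221 over probes well above background on all 8 arrays, 304 with trend and robust moderation, 8 and 5 with the slide as a random and a fixed block, 0 with the replicate block (2519 at an unadjusted p under 0.05) and 3 from its 4 arrays alone, which leave fewer degrees of freedom. Without a filter on dim probes it was 2, the difference 2038, the uninduced lines 1996, the seed site value -0.041 and the correlation 0.056. Quantile normalization gave a correlation of 0.069, and the replicate block 2089 genes for the difference. The slide as a random block, where the list test changed as well, left 7 lists in the HIC1 line. With an estimated correlation 3, 0 and 3 lists passed in the HIC1 line, the miR-212/132 line and the difference, and fry passed 24 in the HIC1 line, 16 in the miR-212/132 line and 22 for the difference. The longer seed site gave -0.248 and the 5p seeds 0.003. Bright probes without HIC1 DOX+ replicate 1 gave 4621 genes in the HIC1 line.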

Other observations

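The searches for seed sites in the probe sequences were chosen only after the data were seen, and the genes singled out in this part were chosen after their values were seen. Several lists without a call held genes that differed between the uninduced lines, where 19% of all genes tested passed. Interferon-stimulated genes had 10 higher and 7 lower of 31 in the uninduced HIC1 line (16 and 8 adjusted over the list alone, median 0.46, adjusted p = 0.133), and p53 targets 7 higher and none lower of 29 (9 and 2, median 0.10, adjusted p = 0.231). Immediate early genes had 9 higher and 4 lower of 32 (11 and 5, median 0.07, adjusted p = 0.52), with FOS at 2.58, EGR1 at 1.58 and DUSP6 at 1.56. Estrogen response genes had 9 higher and 4 lower of 35 (10 and 4, median -0.06, mean 0.12, test down, adjusted p = 0.797), with IGFBP5 at 2.57 and PDZK1 at 2.24. Ephrins and their receptors had 6 higher and 2 lower of 16 in both adjustments (median 0.12, adjusted p = 0.308), with EPHB6 at 2.26 and EPHB4, a receptor tyrosine kinase, at 0.90. TGF-beta targets had a median of 0.10 over 20 genes. Among them, TGFBI was lower by 1.71 and CDKN2B, a CDK inhibitor, by 1.98, while TGFB1, the ligand gene, was higher by 2.40. Histones had 3 higher and 8 lower of 17 (4 and 8, median -0.28, adjusted p = 0.151).

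Besides the largest changes, the HIC1 line gained RNA of OLFML3, a secreted glycoprotein (4.06), P3H2, a collagen prolyl hydroxylase (3.69), and ITM2C (3.81). It lost RNA of S100A9, a calcium-binding protein of inflammation (-3.42), and GRIK3, a glutamate receptor subunit (-3.36), which were both well above background on all 4 arrays. KLK12, a kallikrein protease, was also lower (-3.57), but lay at 0.36 and 0.17 against miR-212/132 DOX- on the same slides, so that its fall rested on the HIC1 DOX- arrays of slide 3.

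Probes that contain a site for the seed shared by miR-212 and miR-132 were tested as a hypothesis of targeting by the induced miRNAs. Over 196 genes the median log2 fold change was -0.05 against 0.02 for the others in the miR-212/132 line, 57.1% were lower against 45.8%, and 5 passed, all lower, which were DAZAP2 (-0.92), EGR1 (-0.86), INPP5K (-1.12), PNKD (-1.23) and SH3BP5 (-0.82). These 5 calls did not hold without any 1 of 6 arrays, without a filter on dim probes, from the 4 arrays of the line alone or with a replicate block, settings in which no gene passed as lower. The difference of these medians, -0.068, was -0.117 without miR-212/132 DOX- replicate 1, -0.041 without a filter on dim probes and -0.047 with normexp from negative control spots. Only 0.1% of 9653 7-mers had a mean t as low as theirs (-0.823), GACTGTT alone was the lowest of all (118 genes, mean t -1.15) and ACTGTTA ranked 3 (-1.039). A sequence effect of the arrays was argued against by the HIC1 line, where 41.97% of 7-mers were as low (mean t 0.128), and the share stayed at 0.08% after regression on GC content. Targeting by the induced miRNAs is thus a candidate explanation for the small shift of these genes, as a hypothesis, and the 5p seeds gave no like shift (54.77% of 7-mers as low, 289 genes).

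HIC1 signal in the uninduced HIC1 line, at least 2.42-fold above the other line, raised the hypothesis that leaked HIC1 already changes these cells. Across 21081 genes, the difference between the uninduced lines correlated with the response to HIC1 with r of 0.098 and 0.095 from separate HIC1 DOX- arrays. Genes are not independent replicates, and differences between the lines that predate the construct could give the same value, so that the leak cannot be told apart from them. Both HIC1 DOX- arrays also lay on slide 3, and the other arrays used here on slides 1 and 2. A slide effect would enter the 2 sides with opposite signs and lower r.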
